A study of Homo sapiens with 36 samples.

How the data were processed

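RNA-seq gene counts of 36 libraries from KOLF2.2J, an established human induced pluripotent stem cell line, were analysed in 12 groups of 3 libraries. Per the labels, total RNA was depleted of ribosomal RNA (RiboErase), prepared with the KAPA RNA HyperPrep kit and sequenced on a NovaSeq X. The labels list 3 extraction kits without saying which library had which. In each of 4 experiments the parental line (WT) was differentiated beside edited clonal lines. A knockout (KO) line carries a premature termination codon in the gene named. A reverted (REV) line is a knockout line whose codon was edited back to wild type. Each KO or REV group holds 3 clonal lines; a line label such as A09 belongs to one gene's set of lines, and the same label under another gene is another line. Labels do not say whether REV lines of a gene come from 1 or several KO lines, so their independence as editing events is unknown. P-values pool the spread over all groups of a fit and hold for these lines only. The series' design text speaks of biological replicates, but nothing in the labels says that the 3 parental libraries of an experiment came from separately thawed or passaged cultures, so the spread within WT is that between these differentiations or libraries only. It also counts fewer libraries than were analysed here. Sequencing lane, read from the library names, was 1 for the PPARG experiment, 5 for the EPAS1 and the GCM1/GRHL1 experiments and 7 for the PAX6 experiment, so no comparison within an experiment crosses lanes.

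The authors deposited whole-number gene counts that were not normalized. Per the submitters' processing notes, STAR, Salmon and featureCounts were used with genome build GRCh38. Their versions, their roles, the annotation release and the strand setting are not given in the sources used here, so antisense and overlapping genes are uncertain, as are members of families with near-identical copies (CGB, PSG, LGALS, NLRP, PCDHA and histone genes). The authors also deposited estimated counts per gene, taken here as Salmon output and rounded to whole numbers for one alternative, which moved no value by more than 0.5. Transcript tables and TPM tables were not used. The count table holds 38592 gene identifiers, of which 38568 came with a symbol; 53 symbols stood on more than 1 identifier. Positions on GRCh38 from GENCODE release 29 were matched by identifier for 34390 of them. The deposited mapping statistics list reads that name no gene, which stayed out of library sizes and tests: reads in no annotated feature were 10.1% to 36.6% of uniquely mapped reads, multimapping reads 6.4% to 14.4% and unmapped reads 4.0% to 7.2% of all reads. No 2 libraries of a group had identical counts.

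Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust dispersion estimation, robust quasi-likelihood fits and two-sided quasi-likelihood F tests, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. All groups of an experiment shared one fit of group means (9 PAX6, 12 EPAS1, 9 GCM1/GRHL1 and 6 PPARG libraries). Parental groups of different experiments were compared in a fit of all 27 primitive syncytium libraries. Expression levels (CPM) are on the TMM scale of the fit, unless a library total is named, and are given as mean ± SD over 3 libraries. Log2 fold changes are given with their SE. For a gene with 0 counts in a group the fold is a bound against 3 counts over the group. For 1 to 3 counts in a group the counting interval of the ratio is given. Bounds and intervals cover counting error only. With totals of 18.5 to 34.7 M counts, a gene at 1 CPM had about 18.5 to 34.7 counts per library.

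The design, the alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. The rule names the edited gene, the 8 largest rises and 8 largest falls among called genes whose 3 libraries of one group all lie above those of the other and whose higher mean is at least 1 CPM (5 each way for the interaction), up to 4 members of each called list in its direction plus up to 2 called the other way, and the 4 highest members of the model's marker list. It leaves out clones, small RNAs, antisense and divergent transcripts, pseudogenes, XIST and Y-linked genes; those stay in the counts. Lists covered cell types of both lineages, markers of other cell types that such cultures could hold, and pathways. Members counted for a list are those that passed the filter on low counts and were tested. Each was tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, in 179 tests; lists with under 5 tested members were not run. Each was repeated with an estimated correlation and with fry, which asks whether members move one way and does not compare a list with other genes. Every list called with the preset correlation was lost with an estimated one.

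Each step was tested on simulated counts with 200 changed genes drawn from the real means and library sizes. At a log2 change of 1, recovery was 88.1% for PAX6 KO against WT, 94.0% for EPAS1 REV against WT at 20% oxygen, 92.5% for oxygen in WT, 88.1% for GCM1 REV, 89.6% for GRHL1 REV and 97.0% for PPARG REV. At a change of 0.5 it was 56.7%, 56.7%, 64.2%, 49.3%, 50.7% and 83.6% in the same order. For comparisons sharing libraries, 20 simulations gave overlap and correlation with groups unchanged, not with a shared group changed.

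In the EPAS1 experiment the same clonal lines (A03, A05, A06) were differentiated at both oxygen levels, so line labels pair those libraries by design. Deviations from group means correlated across genes by 0.13, 0.18 and 0.03 between the 2 libraries of A03, A05 and A06, against highest values of 0.17, -0.03 and 0.04 with another line. For the parental numbers 1, 2 and 3 these correlations were 0.06, 0.04 and 0.04 against 0.00, 0.00 and 0.01. Main fits had no block for line; the blocked fit was an alternative.

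Alternatives were RLE size factors, no filter on low counts, the estimated counts, fits without robust estimation, DESeq2 1.42.0, fits of the compared groups alone, all 27 primitive syncytium libraries in one fit, each library left out in turn, a block for line or replicate number, and other list tests. Fits without line B01 and without line A05 were added after the data were seen. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.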

Results

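Gene expression was measured by total RNA-seq in KOLF2.2J human induced pluripotent stem cells and their edited derivatives after 2 differentiations. Primitive syncytium, a trophoblast culture in which cells fuse into a syncytium, was collected at day 6. Cortical brain organoids patterned toward dorsal forebrain were collected at day 9. Primitive syncytium libraries came from a PPARG experiment (3 REV, 3 WT), an EPAS1 experiment (3 REV and 3 WT at each of 20% and 3% oxygen) and a GCM1/GRHL1 experiment (3 GCM1 REV, 3 GRHL1 REV, 3 WT). Organoid libraries came from a PAX6 experiment (3 KO, 3 REV, 3 WT). Libraries held 20.9 to 25.3 M counts in the PPARG experiment, 21.8 to 34.7 M in the EPAS1 experiment, 23.0 to 31.7 M in the GCM1/GRHL1 experiment and 18.5 to 30.6 M in the PAX6 experiment. Parental cultures carried the markers of their model. The hormone subunit gene CGA stood at 1557 ± 234 CPM in PPARG WT, 3049 ± 898 in EPAS1 WT at 20% oxygen and 4211 ± 716 in GCM1/GRHL1 WT (SD, n = 3 each). PGF, the placental growth factor gene, stood at 1009 ± 47.0, 1626 ± 134 and 1216 CPM in the same groups. Next highest were SDC1 (786 CPM) and CYP19A1 (693 CPM) in PPARG WT, SDC1 (1325 CPM) and ERVV-2 (1136 CPM) in EPAS1 WT, and ERVW-1 (1096 CPM) in GCM1/GRHL1 WT. In organoid WT, the WNT antagonist gene SFRP1 was at 1615 ± 80.5 CPM and the forebrain homeobox gene OTX2 at 383 ± 4.80 CPM, followed by SFRP2 (379 CPM) and TLE4 (312 CPM).

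**Figure D1:**
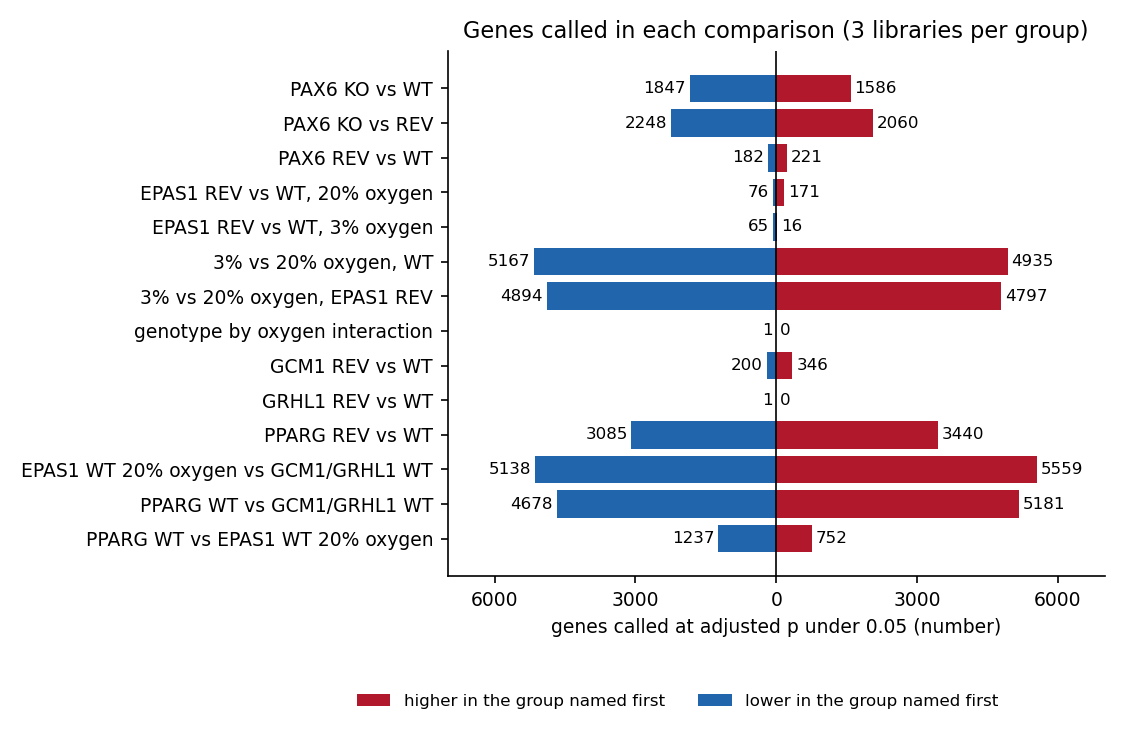
Bars give the number of genes called at an adjusted p under 0.05 in each of the 14 comparisons, with genes higher in the group named first to the right of 0 and lower genes to the left; every group has 3 libraries. The oxygen comparisons called 10102 and 9691 genes, PPARG REV against WT 6525, and GRHL1 REV against WT 1.

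The edited codon of each gene lay in a coding exon on GRCh38, per the coordinates in the labels. That of PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062), a homeobox regulator of eye and forebrain development, was at 31794736 to 31794738 in exon 8 of 13. That of EPAS1 (ENSG00000116016, chromosome 2, 46293667 to 46386703), which encodes the hypoxia-inducible factor HIF-2 alpha, was at 46356246 to 46356248 in exon 3 of 16. That of GCM1 (ENSG00000137270, chromosome 6, 53126964 to 53148829), a driver of trophoblast fusion, was at 53134133 to 53134135 in exon 3 of 6. That of GRHL1 (ENSG00000134317, chromosome 2, 9951693 to 10002277), an epithelial transcription factor, was at 9963965 to 9963967 in exon 6 of 16. That of PPARG (ENSG00000132170, chromosome 3, 12287368 to 12434356), a nuclear receptor of lipid metabolism and placental development, was at 12381411 to 12381413 in exon 3 of 7. Gene counts do not show the codon itself.

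Transcripts of the edited genes were present in every group. PAX6 stood at 217 ± 30.9 CPM in KO, 300 ± 3.56 in REV and 309 ± 21.6 in WT organoids. It was 1.43-fold lower in KO than in WT (log2 fold change -0.51 ± 0.08 SE, adjusted p = 6.4e-05) and 1.39-fold lower than in REV (-0.47 ± 0.08, adjusted p = 1.4e-04). REV and WT differed by -0.04 for PAX6 (adjusted p = 0.91). EPAS1 was at 944 ± 149 CPM in REV and 1055 ± 33.3 in WT at 20% oxygen (-0.16 ± 0.09, adjusted p = 0.45). It was at 966 ± 7.52 and 984 ± 14.9 CPM at 3% oxygen (-0.03 ± 0.09, adjusted p = 0.89). GCM1 was at 419 ± 46.8 CPM in GCM1 REV and 350 ± 25.8 in WT (0.26 ± 0.08, adjusted p = 0.077). GRHL1 was at 284 ± 5.17 CPM in GRHL1 REV and 245 ± 11.7 in WT (0.21 ± 0.14, adjusted p = 0.47). PPARG was at 57.7 ± 3.34 CPM in REV and 59.6 ± 2.83 in WT (-0.05 ± 0.06, adjusted p = 0.54).

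PAX6 KO organoids were compared with WT to ask which genes change without an intact PAX6 codon at the start of dorsal forebrain patterning. Transcripts of HES5 and NR2E1, genes of neural progenitors, were nearly lost. HES5, a Notch effector of neural progenitors, fell 55.7-fold, from 54.8 ± 14 to 1.13 ± 1.15 CPM (log2 fold change -5.80 ± 0.52 SE, adjusted p = 6.5e-04). NR2E1, an orphan nuclear receptor of forebrain stem cells, fell 105-fold, from 8.11 ± 1.48 to 0.0826 CPM (-6.71 ± 0.32, adjusted p = 6.6e-15). DLX5 and FOXA1 rose from low levels. DLX5, a homeobox gene of the ventral forebrain, went from 0.531 ± 0.0962 to 8.97 ± 3.69 CPM (4.04 ± 0.30, adjusted p = 1.1e-08). FOXA1, a forkhead pioneer factor, went from 5.61 ± 0.767 to 45.9 ± 5.28 CPM (3.03 ± 0.13, adjusted p = 3.7e-13).

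Further large rises were in SLITRK6, a neuronal membrane protein gene (4.62 ± 0.34, 16.9 ± 7.20 against 0.679 ± 0.0964 CPM), DLX6 (3.83), RSPO3, a WNT agonist gene (3.66) and SEMA3E (3.22). GDF10, a BMP-family ligand gene, stood at 30.1 ± 2.38 against 2.69 ± 0.393 CPM (3.48 ± 0.13), and DKK1, a WNT antagonist gene, was higher by 3.37. Further falls were in EDN1, the endothelin 1 gene (-4.76), CLVS1 (-4.73), RLBP1 (-4.60), KLHL14 (-4.48) and DMRT3, a transcription factor gene of the dorsal telencephalon (-4.35 ± 0.40, adjusted p = 5.2e-09). DIPK1C had no count in KO against 350 counts in WT, at least 105-fold lower against 3 counts over the group. In all, 3433 of 19936 genes (17.2%) were called, 1586 higher and 1847 lower in KO. Reads in no annotated feature were 24.5% to 31.1% of uniquely mapped reads in KO, 31.9% to 35.6% in WT and 30.5% to 36.6% in REV, so this share differed between KO and WT as well. Of 816 with an absolute log2 fold change over 1, 670 were lower. The groups did not overlap for 35.7% of genes, where chance gives 10%.

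**Figure D2:**
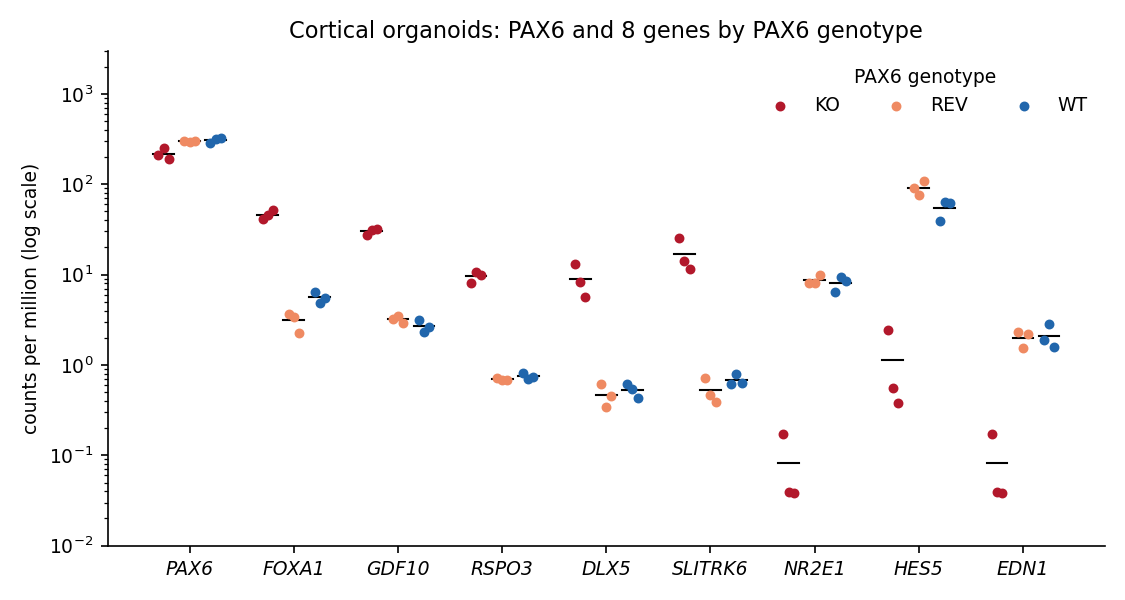
Points are the CPM (log axis) of PAX6 and 8 other genes in the 9 cortical organoid libraries, with KO in red, REV in orange and WT in blue, and black lines mark the mean of 3 libraries. FOXA1 lay at 45.9 CPM in KO against 3.13 in REV and 5.61 in WT, and HES5 at 1.13 against 91.9 and 54.8.

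Among the gene lists, that of the ventral forebrain and hypothalamus was higher in KO (camera, median 1.18, adjusted p = 2.1e-04; adjusted p = 0.088 with an estimated correlation). Of its 23 genes 6 passed the filter on low counts, which favours rises in genes low in WT such as DLX6. Called higher were 3 (5 adjusted over the list alone): DLX5, DLX6 and GAD1, a GABA synthesis gene (1.08 ± 0.22, adjusted p = 7.3e-04). DLX1 was at 1.29 (adjusted p = 0.067). The cell cycle list was higher by a median of 0.20 (adjusted p = 5.8e-07; adjusted p = 0.58 with an estimated correlation). Of its members 14 of 30 were called higher (16 adjusted over the list alone), among them the cyclin gene CCNA2 (0.43 ± 0.07) and the mitotic kinase gene AURKA (0.36). The list of mitochondrially encoded respiratory genes was lower (median -0.51, adjusted p = 0.0042; adjusted p = 0.60 with an estimated correlation). Called was 1 of 13, also adjusted over the list alone: MT-ND2, 397 ± 33.5 against 610 ± 77.8 CPM (-0.62 ± 0.11). Mitochondrial transcripts made up 0.63% to 0.82% of counts in KO libraries and 0.87% to 1.49% in WT.

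Other lists did not pass, and most held members called both ways. Of the neuroepithelium list 5 members were higher and 13 lower of 26 (adjusted p = 0.056; 5 and 14 adjusted over the list alone). Of the forebrain and dorsal telencephalon list 7 were higher and 10 lower of 27 (adjusted p = 0.31; 9 and 10 adjusted over the list alone; median 0.01, mean -0.60). Of the eye field list 0 were higher and 4 lower of 12, of the neural crest and roof plate list 6 and 4 of 22 and of the neuron list 7 and 6 of 23. Of the WNT list 5 were higher and 3 lower of 19, of the midbrain and hindbrain list 2 and 2 of 11 and of the surface ectoderm list 4 and 3 of 17. Of the remaining lists, counts higher and lower were 3 and 2 of 24 for hypoxia, 5 and 4 of 22 for glycolysis, 2 and 3 of 18 for pluripotency and 2 and 1 of 7 for mesoderm. They were 3 and 2 of 19 for mesenchyme, 4 and 3 of 28 for p53 targets and 3 and 3 of 22 for the unfolded protein response. With DESeq2, 59.6% of called genes were higher in KO, against 46.2% here. The count of called genes was 2140 without KO replicate 3, 2198 without WT replicate 2 and 1995 without WT replicate 3.

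Against PAX6 REV, whose lines went through editing and cloning as well, KO organoids showed the loss of HES5 (91.9 ± 16.7 to 1.13 CPM, -6.55 ± 0.51, adjusted p = 2.5e-04) and NR2E1 (-6.82 ± 0.32, adjusted p = 4.4e-15). Higher were FOXA1 (3.89 ± 0.14, adjusted p = 2.3e-14), SLITRK6 (4.99 ± 0.36), DLX5 (4.22), RSPO3 (3.77) and GDF10 (3.24). Also lower was BARHL1, a homeobox gene of the diencephalon and hindbrain (30.9 ± 9.69 to 0.455 CPM, -6.19 ± 0.68, adjusted p = 0.0014). NEUROD4, a proneural factor gene (59.3 ± 4.89 to 1.63 ± 1.84 CPM, -5.40 ± 0.58, adjusted p = 0.0013), fell too, as did KLHL14 (-5.39), CFAP77 (-4.97) and EDN1 (-4.71). DIPK1C was at least 44.0-fold lower (0 counts against 1.92 ± 0.291 CPM). DMRTA2, a regulator of cortical progenitors, was higher in KO than in REV (13.6 ± 1.55 against 1.12 ± 0.508 CPM, 3.63 ± 0.23, adjusted p = 1.7e-09), as were CUZD1 (3.48) and TTC6 (3.14). In all, 4308 genes (21.6%) were called, 2060 higher and 2248 lower.

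The ventral forebrain list was again higher (median 1.72, adjusted p = 1.4e-04; adjusted p = 0.08 with an estimated correlation). Of the 6 tested members 4 were called (5 adjusted over the list alone), among them DLX1 (2.23 ± 0.55, adjusted p = 0.0048), DLX6 (2.54) and MEIS2 (1.05 ± 0.21, adjusted p = 0.011). DLX1 stood at 0.542 CPM in KO against 0.120 in REV, so the filter favours rises here too. The cell cycle list was higher with 20 of 30 called (26 higher and 1 lower adjusted over the list alone; adjusted p = 1.2e-07; adjusted p = 0.66 with an estimated correlation), including TYMS, the thymidylate synthase gene (0.48 ± 0.07), and MKI67 (0.37). Mitochondrially encoded genes were higher as a list (median 0.48, adjusted p = 7.3e-04; adjusted p = 0.66 with an estimated correlation) with 0 of 13 members called, also adjusted over the list alone. That direction is opposite to the comparison with WT, and mitochondrial transcripts were 0.56% to 0.69% of counts in REV. Called members went both ways in the neuroepithelium (7 higher, 14 lower of 26), forebrain (8 and 12 of 27), neuron (6 and 8 of 23) and WNT (3 and 6 of 19) lists. With DESeq2, 61.9% of called genes were higher against 47.8% here. The count was 2782 without KO replicate 3 and 2475 without REV replicate 1.

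Both contrasts called 2356 genes in the same direction, 1071 higher and 1285 lower in KO, and 3 in opposite directions. The contrasts share the KO libraries. Unchanged groups that shared them gave a mean of 0.25 such genes and at most 1 in 20 simulations, and independent lists of these sizes would share 372. Log2 fold changes correlated across genes by 0.84 (Pearson; 0.52 simulated), with a covariance of 0.227 against 0.0272 simulated, a difference of 0.200. Genes are not independent replicates, and part of the excess over the simulated values may come from the shared libraries.

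PAX6 REV was compared with WT to see what differs once the codon is restored. Higher in REV were WNT1 (1.55 ± 0.751 against 0.135 CPM, 3.54 ± 0.72, adjusted p = 0.031), WNT4 (1.90 ± 0.24, adjusted p = 1.8e-05), and LMX1B, a homeobox gene of the midbrain and hindbrain (2.26 ± 0.38, adjusted p = 8.7e-04). So were the WNT target gene SP5 (2.11 ± 0.36, adjusted p = 0.015) and APCDD1, a WNT inhibitor gene (1.93 ± 0.30, adjusted p = 0.012). CERCAM (2.64), NEUROG2 (2.05) and POU4F1 (1.92) also rose. Lower were DMRTA2 (5.47 ± 1.38 to 1.12 ± 0.508 CPM, -2.32 ± 0.24, adjusted p = 2.4e-05) and CDH1, the E-cadherin gene (-1.79 ± 0.30, adjusted p = 0.0015). EYA4 (-2.12), NRP1 (-1.50), MMRN1 (-1.42), DIO3OS (-1.36), DIPK1C (-1.24) and HS3ST5 (-1.17) also fell. In all, 403 genes (2.02%) were called, 221 higher and 182 lower. Groups did not overlap for 18.4% of genes, against 10% by chance.

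As lists, midbrain and hindbrain genes were higher in REV (3 of 11 called, 7 adjusted over the list alone; median 0.72, adjusted p = 6.3e-05), including IRX2 (0.72 ± 0.12, adjusted p = 0.0017) and IRX3 (0.67), with BARHL1 at 1.93 (adjusted p = 0.11). WNT genes were higher (4 of 19 called, 8 higher and 1 lower adjusted over the list alone; adjusted p = 4.1e-04), including TNFRSF19 (0.99 ± 0.10) and ZNRF3 (0.39). Neural crest and roof plate genes were higher (2 of 22 called, 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.035), namely WNT1 and RSPO2, a WNT agonist gene (94.3 ± 6.70 against 52.0 ± 7.75 CPM, 0.86 ± 0.10). Pluripotency genes were lower as a list (adjusted p = 0.035) with 0 of 18 called, also adjusted over the list alone. TDGF1 was at -2.43 (adjusted p = 0.45) and USP44 at -0.24 (adjusted p = 0.094). Mitochondrially encoded genes were lower (median -1.01, adjusted p = 2.7e-17), 1 of 13 called and all 13 adjusted over the list alone, with MT-ND2 at 329 ± 44.8 against 610 ± 77.8 CPM. For the midbrain, WNT and mitochondrial lists adjusted p = 0.24 with an estimated correlation, for neural crest 0.31 and for pluripotency 0.25. Of the forebrain list 5 members were higher and 7 lower of 27, and of the surface ectoderm list 0 and 3 of 17. Of the neuron list 3 were higher and 1 lower of 23, of the mesenchyme list 4 and 1 of 19, of the neuroepithelium list 1 and 4 of 26, of the eye field list 1 and 1 of 12 and of the ventral forebrain list 0 of 6. The count of called genes was 158 without REV replicate 1, 241 without REV replicate 3 and 162 without WT replicate 1. It was 731 without a filter on low counts and 759 in a fit of these groups alone.

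EPAS1 encodes an oxygen-sensitive factor, and its lines were differentiated at both oxygen levels. In WT primitive syncytium, 3% oxygen lowered INSL4 and GCM1 and raised EGLN3 and SLC2A3. INSL4, a placental hormone gene, fell 20.7-fold from 45.1 ± 6.70 to 2.17 ± 0.370 CPM (-4.37 ± 0.38, adjusted p = 3.7e-06). GCM1 fell from 533 ± 21.8 to 218 ± 6.62 CPM (-1.29 ± 0.07). The hypoxia-induced prolyl hydroxylase gene EGLN3 rose from 26.3 ± 1.24 to 172 ± 1.48 CPM (2.71 ± 0.10, adjusted p = 4.5e-12), and SLC2A3, a glucose transporter gene, from 1128 ± 78.9 to 3664 ± 203 CPM (1.70 ± 0.10). Of 16837 genes, 10102 (60.0%) were called, 4935 higher and 5167 lower at 3% oxygen. Groups did not overlap for 69.8% of genes, where chance gives 10%.

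The largest rises in WT at 3% oxygen were in SLC1A6, a glutamate transporter gene (14.8 ± 0.907 against 0.0725 CPM, 7.65 ± 0.47), LHX5 (5.67) and RGS4, a regulator of G-protein signalling (16.7 ± 2.01 against 0.378 ± 0.141 CPM, 5.42 ± 0.23, adjusted p = 1.3e-11). CD300A (5.22), CHRD, the BMP antagonist chordin gene (4.93), and CA3, a carbonic anhydrase gene (53.2 ± 4.14 against 1.82 ± 0.676 CPM, 4.88 ± 0.19) followed. CD300E had 139 counts against 1 (ratio 20.9 to 4718) and CASP14 137 against 1 (20.6 to 4651). The largest falls were in RSAD2, an interferon-induced gene (9.80 ± 1.80 to 0.341 CPM, -4.83 ± 0.36, adjusted p = 2.3e-08), INSL4, DHRS9 (-5.68), TNS4 (-4.36) and ESAM (-4.29). TM4SF1 had 2 counts against 124 (ratio 0.00165 to 0.0508), RIT2 2 against 100 (0.00204 to 0.0633) and SERPINB13 3 against 95 (0.00546 to 0.0812).

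Of the syncytiotrophoblast list in WT, 32 of 36 members were lower and 1 higher at 3% oxygen (33 and 1 adjusted over the list alone). The list was at a median of -1.56 (camera adjusted p = 2.1e-10; adjusted p = 0.32 with an estimated correlation). These included HOPX (339 ± 26 to 87.3 CPM), the aromatase gene CYP19A1 (1025 ± 54.7 to 351 ± 20.4 CPM) and OVOL1 (-1.36). CGA stood at 673 ± 47.1 CPM at 3% oxygen against 3049 ± 898. The exception was PAPPA2, a protease gene acting on IGF-binding proteins, which rose from 164 ± 3.81 to 453 ± 21.5 CPM (1.47 ± 0.14). Of the amnion list 12 of 13 were higher and 1 lower (the same counts adjusted over the list alone; median 1.36, adjusted p = 1.3e-05; adjusted p = 0.12 with an estimated correlation). They included VTCN1 (94.4 to 318 CPM), ISL1 (3.85), BNC1 (1.35) and CDH10 (6.81 to 142 ± 8.20 CPM), with ANXA1 lower (-1.77). Hypoxia-inducible genes were higher in 21 and lower in 4 of 28 (the same adjusted over the list alone; adjusted p = 1.1e-05; adjusted p = 0.38 with an estimated correlation). LOXL2 (2.55), P4HA2 (2.01) and KDM4B (1.31) rose, and SERPINE1 (684 to 129 CPM) and ADM (-1.11) fell. Glycolysis genes were higher in 20 of 22, also adjusted over the list alone (median 0.81, adjusted p = 1.2e-07; adjusted p = 0.32 with an estimated correlation). They included the lactate transporter gene SLC16A3 (2.42), PDK1 (1.59) and PFKFB3 (1.54).

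All 13 mitochondrially encoded respiratory genes fell in WT, also adjusted over the list alone (median -1.04, adjusted p = 2.3e-05; adjusted p = 0.40 with an estimated correlation), among them MT-CO2 (3966 ± 220 to 1072 ± 103 CPM), MT-CO3 (-1.13) and MT-CO1 (-0.98). Their share of all counts went from 3.37% to 3.69% at 20% oxygen to 1.68% to 2.06% at 3%. Mesenchyme and matrix genes were higher in 14 and lower in 4 of 21 (also adjusted over the list alone; adjusted p = 0.0016; adjusted p = 0.32 with an estimated correlation). The collagen genes COL3A1 (22.8 to 126 ± 12.5 CPM), COL1A1 (1.64) and COL5A1 (1.14) and LUM (1.48) rose, and FBN1 (-2.10) and TWIST2 (-1.52) fell. Genes of the unfolded protein and integrated stress response were lower in 18 and higher in 2 of 23 (also adjusted over the list alone; adjusted p = 3.5e-05; adjusted p = 0.32 with an estimated correlation). DNAJB9 (-1.69), SDF2L1 (-1.62), CRELD2 (-1.48) and TRIB3 (-1.35) fell, and PHGDH (0.24) and VLDLR (0.17) rose. Lists not called had members both ways: cytotrophoblast 8 higher and 8 lower of 21 (median -0.16, mean 0.04), extravillous trophoblast 7 and 8 of 20 (median 0.13, mean -0.10), and epithelial 12 and 11 of 38. Higher and lower members were 8 and 9 of 27 for the PPAR-linked list, 17 and 9 of 30 for cell cycle, 5 and 13 of 28 for p53 targets, 5 and 2 of 13 for pluripotency, 3 and 1 of 5 for mesoderm and 2 and 3 of 7 for endoderm.

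EPAS1 REV lines responded to oxygen in the same sense. At 3% oxygen GCM1 fell from 440 to 193 CPM (-1.19 ± 0.07), EGLN3 rose from 21.1 ± 3.62 to 172 ± 16.6 CPM (3.02 ± 0.10), and RGS4 rose from 0.201 ± 0.131 to 15.7 ± 2.06 CPM (6.28 ± 0.25, adjusted p = 6.9e-12). CASP14 was at least 33.7-fold higher and SERPINB13 and CARD16 at least 35.9-fold and 33.2-fold lower, each against 0 counts, taken as 3 over the group. Other large rises were SLC1A6 (6.61), CD300A (6.60), STMN2 (5.99), RAB37 (5.83) and DLK1 (5.58), and CD300E had 142 counts against 2 (ratio 16.8 to 517). Other falls were CGB5, a chorionic gonadotropin beta gene with near-identical copies (99.8 ± 55.1 to 3.21 ± 0.265 CPM, -4.96 ± 0.50), DHRS9 (-5.12) and IL7R (-4.95). RIT2 (3 counts, ratio 0.00363 to 0.0531), BSND (3 counts, 0.00366 to 0.0534) and AGXT2 (2 counts, 0.00204 to 0.0634) were nearly lost. In all, 9691 genes (57.6%) were called, 4797 higher and 4894 lower. Groups did not overlap for 58.9% of genes, where chance gives 10%.

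**Figure D3:**
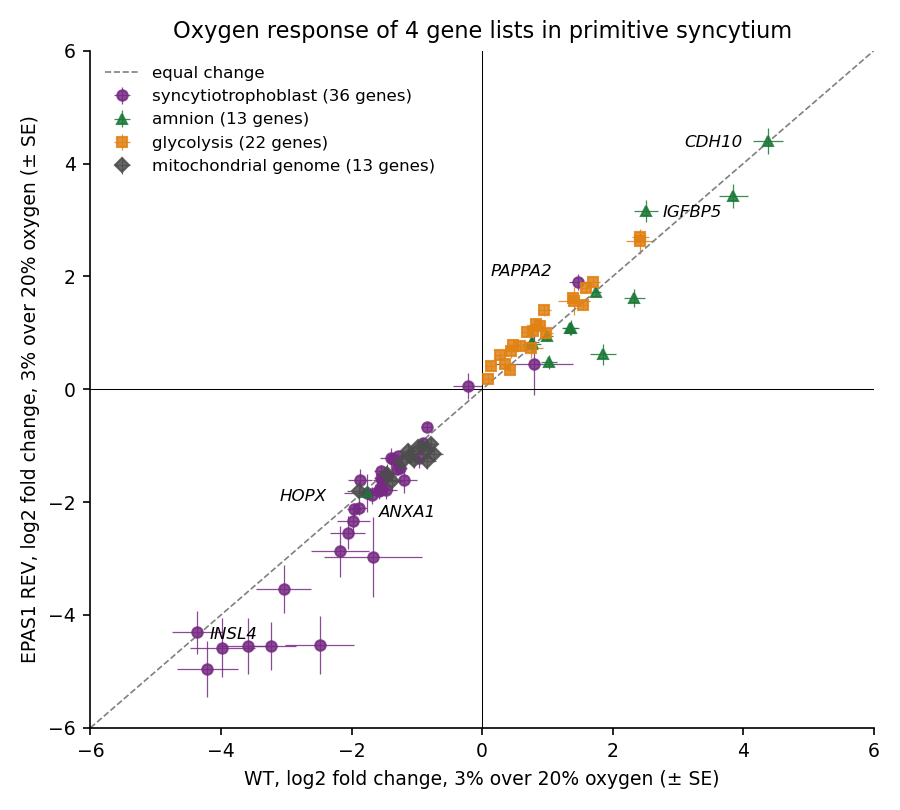
Each point is a member of a gene list, with its log2 fold change (3% over 20% oxygen, ± SE) in WT on the x axis and in EPAS1 REV on the y axis; the dashed line marks equal change. Syncytiotrophoblast genes had medians of -1.56 in WT and -1.76 in REV, amnion genes 1.36 and 1.08, glycolysis genes 0.81 and 1.02 and mitochondrial genes -1.04 and -1.19.

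In REV, 33 of 36 syncytiotrophoblast genes were lower and PAPPA2 higher (1.90) at 3% oxygen (the same adjusted over the list alone; adjusted p = 2.6e-12), with HOPX at -2.13, CYP19A1 at -1.45 and GREM2 at -1.41. Of the amnion list 12 of 13 were higher (the same adjusted over the list alone; adjusted p = 2.2e-05), including IGFBP5 (95.9 ± 27.3 to 859 ± 167 CPM), CDH10 (4.40) and VTCN1 (1.73), with ANXA1 lower (-1.82). Hypoxia-inducible genes were higher in 22 and lower in 3 of 28 (the same adjusted over the list alone; adjusted p = 1.3e-06), including LOX (3.15) and PLOD2 (1.30). Glycolysis genes were higher in 21 of 22 (22 adjusted over the list alone; adjusted p = 2.2e-10), including SLC16A3 (2.70), SLC2A3 (1.90) and PDK1 (1.79). All 13 mitochondrial genes were lower, also adjusted over the list alone (adjusted p = 1.6e-06), with MT-CO2 at -1.80. Their share of counts went from 3.2% to 3.57% to 1.35% to 2.06%. Matrix genes were higher in 13 and lower in 5 of 21 (6 lower adjusted over the list alone; adjusted p = 0.02), with COL3A1 at 2.52 and SPARC at 1.41. Stress-response genes were lower in 17 and higher in 1 of 23 (the same adjusted over the list alone; adjusted p = 2.2e-05). The p53 target list was lower (14 lower and 4 higher of 28, also adjusted over the list alone; adjusted p = 0.035), including the cell cycle inhibitor gene CDKN1A (144 to 74.1 CPM) and AEN (-1.25), with DDB2 (0.99) and CCNG1 (0.71) higher. The cell cycle list was higher (18 higher and 7 lower of 30, also adjusted over the list alone; adjusted p = 0.025), including TOP2A (293 ± 16.1 to 543 ± 32.3 CPM), with CDC6 (-1.12) and RRM2 (-0.76) lower. With the line as a block the cell cycle list was no longer called (adjusted p = 0.057). For the syncytiotrophoblast, hypoxia, glycolysis, matrix and stress lists adjusted p = 0.32 with an estimated correlation. It was 0.15 for amnion, 0.34 for mitochondrial genes, 0.37 for p53 targets and 0.65 for cell cycle. Lists not called were cytotrophoblast (7 higher, 7 lower of 21), extravillous trophoblast (9 and 8 of 20), epithelial (13 and 12 of 38), PPAR-linked (11 and 7 of 27), pluripotency (4 and 3 of 13), mesoderm (2 and 1 of 5) and endoderm (1 and 4 of 7).

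The oxygen responses of WT and REV shared 8389 called genes in the same direction and 2 in opposite directions, where independent lists would share 2908, and their log2 fold changes correlated across genes by 0.91. These contrasts share no library. The difference between the responses, tested as an interaction, called 1 gene with edgeR (1327 at an unadjusted p under 0.05; 15 with DESeq2, 13.3% of them higher). That gene was GPRC5A, a retinoic acid-induced membrane receptor gene: it rose with 3% oxygen from 15.1 ± 1.38 to 50.3 ± 1.49 CPM in WT and stood at 41.4 ± 6.84 and 55.6 ± 4.31 CPM in REV (interaction -1.30 ± 0.15, adjusted p = 0.0025). As lists, glycolysis had a larger response in REV (median 0.22, adjusted p = 1.5e-04; adjusted p = 0.77 with an estimated correlation) with 0 of 22 members called, also adjusted over the list alone. LDHA was at 0.45 (adjusted p = 0.58). Mesenchyme genes had a smaller one (median -0.17, adjusted p = 0.0025; adjusted p = 0.69 with an estimated correlation) with 0 of 21 called (3 lower adjusted over the list alone). SNAI2 was at -1.15 (adjusted p = 0.13) and CDH2 at -1.09 (adjusted p = 0.54). The other 14 lists were not called and held 0 called members. With the line as a block the interaction called 9 genes. It called 15 without REV replicate 1 at 20% oxygen, 3 without REV replicate 3 at 20% oxygen and 24 without REV replicate 2 at 3% oxygen. The count was 31 without line A05 at both levels, 96 without a filter on low counts and 5 in a fit of all 27 primitive syncytium libraries, where GPRC5A was not among them (-1.29). It was called under every other alternative run.

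ANKRD1, TGFB2 and FGF1 were among the genes higher in EPAS1 REV than in WT at 20% oxygen. ANKRD1, a mechanically responsive gene, rose from 4.89 ± 1.21 to 30.4 ± 10.6 CPM (2.62 ± 0.49, adjusted p = 0.037), TGFB2 from 1.85 ± 0.290 to 10.1 ± 3.08 CPM (2.44 ± 0.44, adjusted p = 0.017) and FGF1 from 0.364 ± 0.0693 to 2.98 ± 1.11 CPM (3.02 ± 0.50, adjusted p = 0.0064). MARCHF4 (3.70 ± 0.64, adjusted p = 0.0085), EDN1 (2.61), NNMT (2.08), TDGF1 (2.02) and TGFB1I1 (1.98) were also higher. Lower was GP6, the platelet collagen receptor gene (1.4 ± 0.319 to 0.203 ± 0.0492 CPM, -2.80 ± 0.47, adjusted p = 0.0057). SPAG4 (-1.19), P2RY12 (-1.10), EFNA3 (-1.04), KNDC1 (-0.95), CYP24A1 (-0.93), IGSF10 (-0.89) and VIT (-0.86) also fell. Of 16837 genes 247 (1.47%) were called, 171 higher and 76 lower. Groups did not overlap for 22.9% of genes, against 10% by chance.

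At 20% oxygen the mesenchyme list was higher in EPAS1 REV (adjusted p = 0.013; median 0.08, mean 0.37). Of its members 5 of 21 were called higher (7 higher and 2 lower adjusted over the list alone). Among them were CDH2, the N-cadherin gene (1.49 ± 0.23, adjusted p = 0.0043), SNAI2, a driver of epithelial to mesenchymal transition (1.10 ± 0.17, adjusted p = 0.0043), COL1A2 (0.47) and LUM (0.45). The p53 list was higher (adjusted p = 0.0013) with the death receptor gene FAS called (1.48 ± 0.35) of 28, also adjusted over the list alone. The cell cycle list was higher (adjusted p = 0.039) with 0 of 30 called, also adjusted over the list alone. The syncytiotrophoblast list was lower (adjusted p = 0.0058) with 1 of 36 called, GCM1 (533 ± 21.8 to 440 ± 25.2 CPM, -0.28 ± 0.07, adjusted p = 0.048). Adjusted over the list alone, 1 was higher and 3 lower. PAPPA2 was at -0.48 (adjusted p = 0.097). The hypoxia list of 28 was lower (adjusted p = 0.0011), with 1 member called each way (2 higher and 9 lower adjusted over the list alone). BHLHE40 fell (-0.34 ± 0.08, adjusted p = 0.031), LOXL2 rose (0.72 ± 0.10, adjusted p = 0.0032) and VEGFA was at -0.38 (adjusted p = 0.058). Lower as lists without a called member in that direction were cytotrophoblast (adjusted p = 0.039; 1 higher of 21, HAND1 at 0.62 ± 0.10; 1 higher and 5 lower adjusted over the list alone) and glycolysis (adjusted p = 0.0058; 0 of 22; 2 lower adjusted over the list alone). So was the stress response (adjusted p = 0.0058; 0 of 23; 2 lower adjusted over the list alone). Each of these 8 lists had an adjusted p = 0.59 with an estimated correlation. Not called were extravillous trophoblast (1 higher of 20), amnion (1 higher of 13), PPAR-linked (1 higher of 27), pluripotency (1 higher of 13), epithelial (0 of 38), mitochondrial (0 of 13), mesoderm (0 of 5) and endoderm (0 of 7). The count of called genes was 507, 86 and 70 without REV replicates 1, 2 and 3, and 51, 91 and 41 without WT replicates 1, 2 and 3. It was 637 without line A05, where the syncytiotrophoblast median was -0.28 (-0.13 with it). It was 906 without a filter on low counts, 506 with DESeq2 and 493 in a fit of these groups alone.

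At 3% oxygen, EPAS1 REV and WT differed in 81 genes with edgeR. GP6 (1.31 ± 0.169 to 0.0995 ± 0.142 CPM, -3.56 ± 0.50, adjusted p = 0.006), RDH13 (64.5 ± 1.88 to 19.5 ± 6.77 CPM, -1.72 ± 0.19, adjusted p = 0.0026) and EPS8L1 (86.1 ± 4.50 to 30.1 ± 2.81 CPM, -1.51 ± 0.12, adjusted p = 1.1e-05), which lie near each other on chromosome 19, were lower in REV. So were TSHZ2 (-1.62), CASC9 (-1.39), the p53-linked long noncoding RNA gene PURPL (-1.15 ± 0.10, adjusted p = 4.1e-05), ELAPOR2 (-0.95) and SOX8 (-0.92). Higher in REV were MX1 (30.1 ± 1.74 to 48.7 ± 13.4 CPM, 0.69 ± 0.14, adjusted p = 0.041), ISG15 (25.8 ± 2.49 to 39.1 ± 5.26 CPM, 0.60 ± 0.11, adjusted p = 0.035) and OAS3 (0.53 ± 0.11, adjusted p = 0.048). ERICD (1.30), RFLNA (0.99), H4C8 (0.55), CLTB (0.51) and GNPDA1 (0.48) rose as well. Line A05 held the highest level of each of these 8 genes, for example 63.7 CPM of MX1 against 44.3 and 38.0 in the other lines and 38.6 of OAS3 against 28.5 and 26.3. Without its library at 3% oxygen 49 genes were called, 8.16% of them higher. Of 16837 genes 81 were called, 16 higher and 65 lower. Groups did not overlap for 27.4% of genes, against 10% by chance. The share of reads in no annotated feature was also lower in REV, at 10.4% to 11.8% against 13.7% to 15.7% in WT, and at 20% oxygen it was 10.1% to 13.3% against 13.3% to 14.1%. At both oxygen levels 19 genes were called in the same direction and 0 in opposite ones. The REV lines were the same, so line differences can recur.

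Lists called at 3% oxygen had no called member. The syncytiotrophoblast list was lower (median -0.34, adjusted p = 1.2e-05; 10 of 36 lower adjusted over the list alone), with ERVV-2, an endogenous retroviral envelope gene, at -0.53 (adjusted p = 0.062). The hypoxia list was lower (adjusted p = 0.0053; 2 of 28 lower adjusted over the list alone), with VEGFA at -0.35 (adjusted p = 0.072). Mitochondrial genes were lower (adjusted p = 0.0069; 0 of 13 adjusted over the list alone). Cell cycle genes were higher (adjusted p = 3.3e-05; 0 of 30 adjusted over the list alone), with PCNA at 0.35 (adjusted p = 0.069). These 4 lists each had an adjusted p = 0.69 with an estimated correlation. The other 12 lists had 1 called member in each of the epithelial (lower, of 38) and p53 (higher, of 28) lists and 0 elsewhere. Of called genes 19.8% were higher here, 42.1% of 140 with RLE scaling and 72.8% of 1138 with DESeq2. The count was 357, 49 and 879 without REV replicates 1, 2 and 3, and 9, 14 and 10 without WT replicates 1, 2 and 3. It was 152 without line A05, where the hypoxia median was -0.09 (-0.17 with it), the mitochondrial one -0.42 (-0.21) with 9 of 13 members called lower, and that of cell cycle 0.09 (0.15). It was 1914 without a filter, 4 in a fit of these groups alone and 1390 with all 27 libraries.

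GCM1 REV was compared with WT of the same experiment to see what differs with the codon restored. Higher in REV were CRH, the corticotropin-releasing hormone gene (1.79 ± 0.38, adjusted p = 0.047), CGB7 (17.9 ± 2.23 to 36 ± 10.9 CPM, 1.01 ± 0.20, adjusted p = 0.046) and LGALS13, the placental galectin 13 gene (11.8 ± 1.14 to 20.1 ± 4.52 CPM, 0.77 ± 0.14, adjusted p = 0.038). WNT1 rose (0.399 ± 0.180 to 2.05 ± 1.12 CPM, 2.33 ± 0.47, adjusted p = 0.04), as did DIRAS2 (2.44), ELDR (2.18), PCOLCE2 (2.07), PADI1 (2.03), CCDC68 (2.02 ± 0.25, adjusted p = 0.018), S100A9 (1.98) and SCN3A (1.90). Without line B01, which stood apart, PCOLCE2 was at 1.39, PADI1 at 1.31 and CRH at 1.20. OLFML2A (-1.54 ± 0.34, adjusted p = 0.046) and LTBP2 (-1.26 ± 0.22, adjusted p = 0.032) were lower. So were NNMT (-1.44), ZMAT4 (-1.24), RGS5 (-1.17 for the called one of 2 identifiers with this symbol), FZD2 (-1.13), GYPC (-1.09) and MT1F (-1.07). Of 18802 genes 546 (2.90%) were called, 346 higher and 200 lower. For 34.8% of genes the groups did not overlap, against 10% by chance.

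Of the syncytiotrophoblast list in GCM1 REV 5 of 37 were called higher and 0 lower (29 and 0 adjusted over the list alone; median 0.55, adjusted p = 1.7e-10). Of the cell cycle list 3 of 30 were lower (19 adjusted over the list alone; median -0.25, adjusted p = 3.3e-07): MKI67 (-0.39 ± 0.09, adjusted p = 0.046), CENPF (-0.44) and CCNA2 (-0.35). The extravillous list was higher (adjusted p = 0.0013) with MYCNUT (0.76) and ITGA1 (0.35) called higher. The fibronectin gene FN1 was lower (-0.60 ± 0.09, adjusted p = 0.023), making 2 and 1 of 20 (8 and 1 adjusted over the list alone). Hypoxia genes were higher as a list (adjusted p = 4.7e-04) though the single called member of 28, LOXL2, was lower (-0.78; also adjusted over the list alone). Stress-response genes were higher as a list (adjusted p = 5.5e-04) with the single called member of 23, VLDLR, lower (-0.39 ± 0.05; 3 higher and 1 lower adjusted over the list alone). Glycolysis was higher (adjusted p = 7.8e-04; 0 of 22, also adjusted over the list alone). Mitochondrial genes were lower (adjusted p = 4.7e-04; 0 of 13; 3 lower adjusted over the list alone), as were p53 targets (adjusted p = 0.044; 0 of 28; 1 higher and 5 lower adjusted over the list alone). For each of these 8 lists adjusted p = 0.55 with an estimated correlation. Not called were cytotrophoblast (2 lower of 22), amnion (2 lower of 13), mesenchyme (2 lower of 22), pluripotency (1 higher, 2 lower of 14), epithelial (1 and 1 of 38), PPAR-linked (1 higher of 27) and endoderm (0 of 8).

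Replicate 1 of GCM1 REV (line B01) stood apart: the antiangiogenic receptor gene FLT1 was at 32.2 ± 41.3 CPM in GCM1 REV with it and at 8.31 ± 2.65 CPM in the other 2 lines, against 1.94 in WT. Without that line GCM1 REV differed from WT in 1873 genes, with 22 of 37 syncytiotrophoblast genes higher and 0 lower, 0 of 30 cell cycle genes higher and 13 lower, and 9 of 28 hypoxia genes higher and 1 lower. Without it the list medians were 0.32 for syncytiotrophoblast (0.55 with it), 0.14 for hypoxia (0.46), 0.12 for extravillous trophoblast (0.33), 0.10 for the stress response (0.28), 0.05 for glycolysis (0.26) and -0.18 for cell cycle (-0.25). The count was 3304 and 1628 without GCM1 REV replicates 2 and 3, and 1, 3 and 1 without WT replicates 1, 2 and 3. It was 1388 without a filter, 31 with the estimated counts, 1107 without robust estimation, 2292 with DESeq2, 1 in a fit of these groups alone and 3371 with all 27 libraries.

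GRHL1 REV differed from the same WT libraries in 1 gene with edgeR (2711 at an unadjusted p under 0.05; 216 with DESeq2, 78.2% of them higher). ZNF717, a zinc finger gene, fell 86.6-fold, from 9.91 ± 0.768 to 0.117 ± 0.102 CPM (-6.44 ± 0.32, adjusted p = 2.1e-06). Lists were called with 0 members called in each. The syncytiotrophoblast list was higher (37 members, median 0.37, adjusted p = 1.7e-08; 2 higher adjusted over the list alone), with LGALS13 at 0.56 (adjusted p = 0.20) and CRH at 1.58 (adjusted p = 0.21). The cell cycle list was lower (30 members, median -0.20, adjusted p = 4.8e-07; 4 lower adjusted over the list alone), with MKI67 at -0.31 (adjusted p = 0.23). Hypoxia was higher (28, median 0.23, adjusted p = 0.004; 0 adjusted over the list alone), as was glycolysis (22, median 0.13, adjusted p = 0.0066; 0 adjusted over the list alone). Extravillous genes were higher (20, median 0.16, adjusted p = 0.015; 1 higher and 1 lower adjusted over the list alone), as were stress-response genes (23, median 0.15, adjusted p = 0.015; 1 lower adjusted over the list alone). Mitochondrial genes were lower (13, median -0.10, adjusted p = 0.015; 1 lower adjusted over the list alone). These 7 lists each had an adjusted p = 0.70 with an estimated correlation, and the other 8 lists had 0 members called. Line B01 of GCM1 REV enters this fit through the shared spread, and without it 3132 genes were called between GRHL1 REV and WT, with 26 of 37 syncytiotrophoblast genes higher and 1 lower. The count was 2897 in a fit of these groups alone, 117 with all 27 libraries, 91 without a filter and 2 with the estimated counts. Log2 fold changes of GCM1 REV and GRHL1 REV, which share their WT libraries, correlated across genes by 0.80 (0.51 simulated), with a covariance of 0.122 against 0.0300 simulated, a difference of 0.0920. They shared 0 called genes with edgeR (0.05 simulated). Part of the excess over the simulated values may come from the shared libraries.

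PPARG REV was compared with WT to see what differs with the codon restored. SDC1, the syndecan 1 gene of the syncytial surface, rose from 786 ± 31.7 to 1464 ± 151 CPM (0.90 ± 0.06, adjusted p = 1.0e-07). KRT18, an epithelial keratin gene, rose from 2378 ± 73.5 to 4549 ± 528 CPM (0.94 ± 0.07), and the glucose transporter gene SLC2A1 from 1570 ± 77.6 to 3057 ± 414 CPM (0.96 ± 0.08). The largest rises were in TRIM58 (1.59 ± 0.174 to 30.5 ± 12.2 CPM, 4.27 ± 0.52, adjusted p = 0.0034) and SIGLEC6, a trophoblast sialic acid receptor gene (3.44 ± 0.95, adjusted p = 0.047). OR2W3 (3.26), TPPP3 (2.13 ± 0.20, adjusted p = 2.4e-06), HRH1 (1.97), TNS4 (1.96), TNNT3 (1.94) and UCP1, the uncoupling protein 1 gene (1.82 ± 0.35, adjusted p = 5.6e-04), also rose. The largest falls were in the neighbouring genes NLRP2 (21.8 ± 1.03 to 0.589 ± 0.516 CPM, -5.17 ± 0.36, adjusted p = 4.5e-05) and NLRP7 (22.8 ± 0.0318 to 0.679 ± 0.586 CPM, -5.05 ± 0.31, adjusted p = 1.1e-05), whose annotated positions overlap, so reads can be shared between them. They were followed by ALG10B (-3.76), SLC18A3 (-3.29), PCDHA5 (-2.64), the skeletal actin gene ACTA1 (-2.62 ± 0.49, adjusted p = 0.013), NXPH2 (-2.52) and NALF1 (-2.35). Of 15334 genes 6525 (42.6%) were called, 3440 higher and 3085 lower. Of these, 504 had an absolute log2 fold change over 1. For 53% of genes the groups did not overlap, against 10% by chance. The common biological coefficient of variation was 0.0537 in this experiment, against 0.0922 and 0.102 in the EPAS1 and GCM1/GRHL1 experiments.

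**Figure D4:**
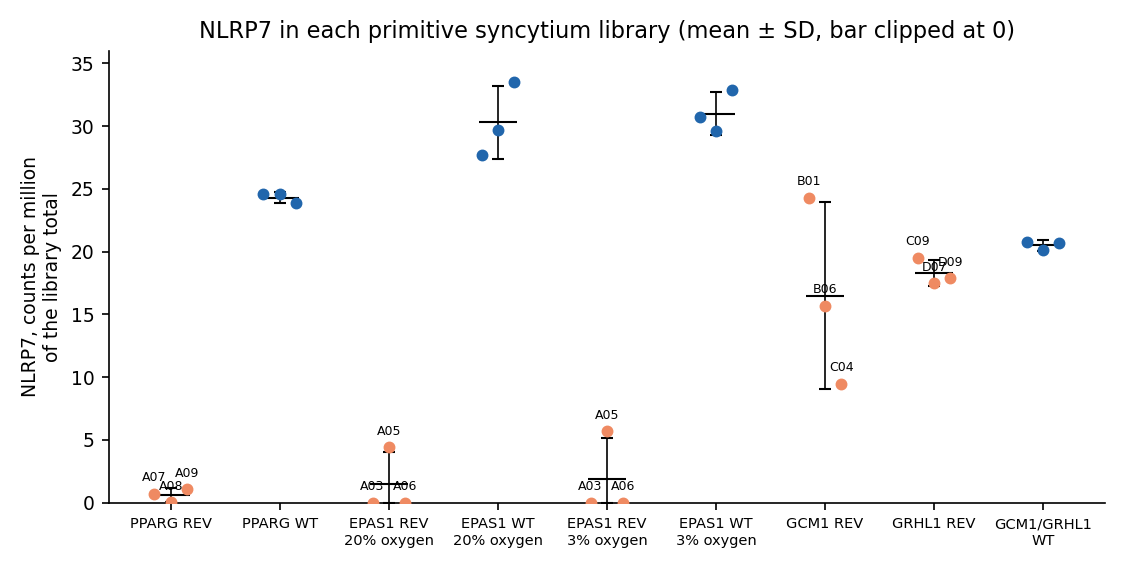
Points are NLRP7 levels in CPM of the library total in the 27 primitive syncytium libraries, REV in orange with the line label and WT in blue; dashes and bars give mean ± SD of 3. PPARG REV lay at 0.625 ± 0.530 against 24.3 ± 0.427 in its WT, and EPAS1 REV at 20% oxygen at 1.47 ± 2.55 against 30.3 ± 2.93.

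Of the syncytiotrophoblast list in PPARG REV 27 of 34 members were higher and 0 lower (31 and 0 adjusted over the list alone; median 0.68, adjusted p = 1.2e-11), including SLC22A11 (1.07), LGALS16 (0.98) and the stress cytokine gene GDF15 (135 to 266 CPM). Cytotrophoblast genes were higher in 12 and lower in 4 of 21 (13 and 4 adjusted over the list alone; adjusted p = 0.0067). ITGB4 (0.73), GATA2 (754 ± 4.08 to 1185 ± 88.0 CPM) and TFAP2C (0.56) rose, and HAND1 (-0.69) and LRP2 (-0.60) fell. Extravillous genes were higher in 11 and lower in 2 of 19 (12 and 2 adjusted over the list alone; adjusted p = 0.0013), including SERPINE1 (384 ± 14.2 to 780 ± 78.5 CPM), with DIO2 lower (-0.28). Epithelial genes were higher in 20 and lower in 5 of 38 (20 and 6 adjusted over the list alone; adjusted p = 0.004), including KRT8 (0.79) and ELF3 (0.90), with MARVELD2 lower (-0.57). PPAR-linked lipid genes were higher in 13 and lower in 3 of 26 (14 and 3 adjusted over the list alone; adjusted p = 0.008). HMGCS2, the ketone synthesis enzyme gene (6.31 to 17.1 ± 3.53 CPM, 1.45 ± 0.14), TXNIP (0.77) and PDK4 (23.7 to 36 ± 1.19 CPM) rose, and FABP5 (-0.79) and ACSL3 (-0.34) fell.

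Hypoxia-inducible genes were higher in 23 and lower in 1 of 28 in PPARG REV (the same adjusted over the list alone; adjusted p = 7.4e-07), including KDM3A (0.57), BHLHE40 (0.50) and VEGFA (0.47), with CA12 lower (-0.42). Glycolysis genes were higher in 19 of 22 (21 adjusted over the list alone; adjusted p = 3.1e-08), including ALDOC (1.35) and GAPDH (0.47). Mitochondrially encoded genes were higher in 7 of 13, also adjusted over the list alone (adjusted p = 0.008), including MT-CO1 (0.51 ± 0.06). Stress-response genes were higher in 18 with 1 lower of 23 (19 and 1 adjusted over the list alone; adjusted p = 1.1e-05), including NUPR1 (0.92), XBP1 (0.62) and ATF4 (0.56). Cell cycle genes were lower in 20 and higher in 2 of 30 (the same adjusted over the list alone; adjusted p = 3.9e-04). CENPE (-0.72) and CENPF (-0.55 ± 0.05) fell, and TPX2 (0.32) and MCM5 (0.14) rose. The mitochondrial list had an adjusted p = 0.55 with an estimated correlation, and each of the other 9 called lists 0.43. Not called were amnion (5 higher, 4 lower of 13), pluripotency (3 and 6 of 12), endoderm (3 and 0 of 7), mesenchyme (6 and 7 of 21) and p53 targets (9 and 10 of 28).

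A run of neighbouring genes on chromosome 20 was higher in PPARG REV. Between HM13 and MAPRE1 (31514410 to 32850405), 13 of 15 genes with a mean of at least 1 CPM were called higher and 0 lower, TPX2 among them, with a median log2 fold change of 0.48 over the 15. The interval was chosen after its values were seen. The largest were BCL2L1, an antiapoptotic gene (1.07), HM13 (0.93), TM9SF4 (0.77) and NOL4L (0.76); PDRG1 (-0.02) and XKR7 (0.09) were not called.

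**Figure D5:**
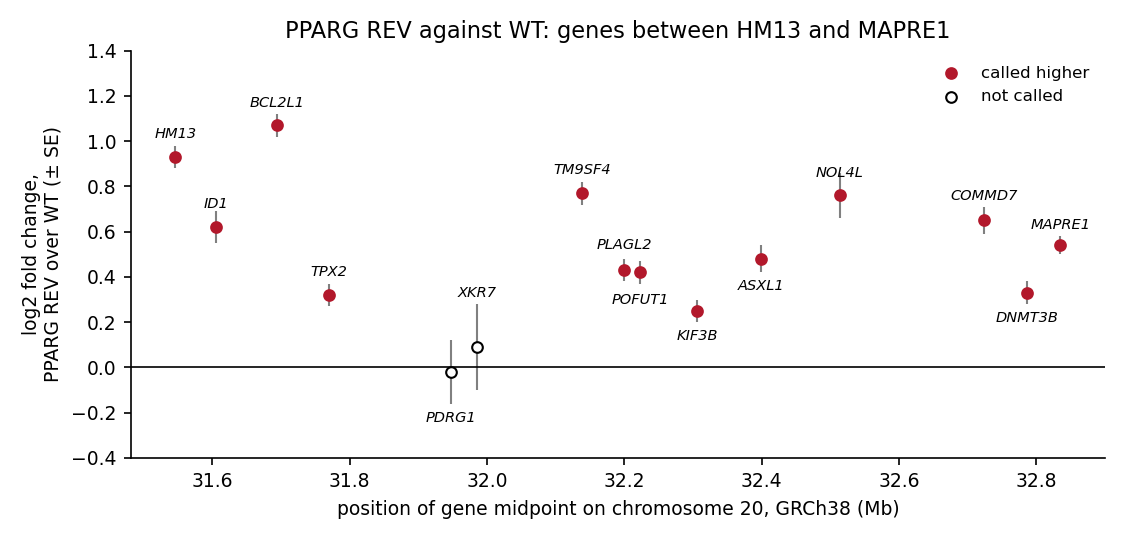
The x axis gives gene midpoints on chromosome 20 (GRCh38, Mb) and the y axis the log2 fold change of PPARG REV over WT with its SE, for 15 genes at 1 CPM or more; filled points were called higher. Values ran from -0.02 at PDRG1 to 1.07 at BCL2L1.

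Reverted lines of different genes were compared with each other to see whether they share differences from WT. Of the 5 comparisons (PPARG, EPAS1 at 20% oxygen, GCM1, GRHL1 and PAX6), at least 2 called the same gene in the same direction for 439 genes, 267 higher and 172 lower (164 with the estimated counts). These counts rest on the calls of each comparison, and those of GCM1 REV fell to 1, 3 and 1 without WT replicates 1, 2 and 3 and to 31 with the estimated counts, so its shared calls do not hold there. EPAS1 REV at 20% oxygen called 41 to 91 genes without 1 WT library and 70 without REV replicate 3, fewer than its shared calls with PPARG REV. The ephrin gene EFNB2 and the plexin gene PLXNA2 were lower, and WNT1 higher, in PPARG, GCM1 and PAX6 REV. IGFBP3, an IGF-binding protein gene, was lower in those 3 and higher in EPAS1 REV. GCM1 and PPARG REV shared 321 calls in the same direction and 6 in opposite ones (110 for independent lists; correlation across genes 0.63). PPARG and EPAS1 REV shared 4 in the same direction and 166 in opposite ones (52.3 in the same direction for independent lists; correlation -0.38). EPAS1 and GCM1 REV shared 1 and 45 (correlation -0.44). PPARG and PAX6 REV, from different lineages, shared 108 and 61 (66.5 for independent lists; correlation 0.08).

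Parental libraries of different experiments were compared. Labels state oxygen only for EPAS1, so it may differ too. GCM1/GRHL1 WT stood apart from both others, and reads in no annotated feature were 23.3% to 30.0% of uniquely mapped reads in its experiment against 10.1% to 15.7% in the EPAS1 and 15.4% to 17.7% in the PPARG experiment. EPAS1 WT at 20% oxygen differed from it in 10697 of 19271 genes (55.5%), 5559 higher and 5138 lower. Higher in EPAS1 WT were TNFSF10, the death ligand TRAIL gene (6.94 ± 0.406 against 0.199 CPM, 5.12 ± 0.95, adjusted p = 1.7e-04), FLT1 (31.8 ± 4.27 against 1.71 ± 0.516 CPM, 4.21 ± 0.88, adjusted p = 5.2e-04) and LEP, the leptin gene (2.69 ± 0.63, adjusted p = 0.0014). MARCHF4 (-3.82 ± 0.61, adjusted p = 6.9e-06), FGF1 (-3.52), ANKRD1 (52.9 ± 11.3 to 5.01 CPM, -3.39 ± 0.58, adjusted p = 6.6e-05), ZEB2 (-3.04), EDN1 (-2.95) and TGFB2 (-2.91 ± 0.52, adjusted p = 1.2e-04) were lower. PPARG WT differed from GCM1/GRHL1 WT in 9859 genes (51.2%), with TNFSF10 (4.35), IGFBP5 (230 ± 12.8 against 29.9 ± 4.46 CPM, 2.94 ± 0.36) and HAS2 (2.92) higher. The nuclear noncoding RNA gene MALAT1 (133 ± 18.7 to 19.3 ± 3.37 CPM, -2.79 ± 0.19, adjusted p = 1.9e-10), MAB21L2 (-3.67) and RBFOX3 (-3.20) were lower. PPARG WT and EPAS1 WT differed in 1989 genes (10.3%). SLC18A3 (2.0 ± 0.50, adjusted p = 0.014) and OAS2 (1.58) were higher in PPARG WT, and APOA2 (-1.81 ± 0.33, adjusted p = 9.7e-04) and CGB3 (95.7 ± 14.3 to 27.8 ± 2.81 CPM, -1.78 ± 0.36, adjusted p = 0.0042) were lower. The shares of genes whose groups did not overlap were 66.1%, 63.8% and 34.1%, where chance gives 10%. PPARG libraries were sequenced on another lane than the other primitive syncytium libraries, so lane and experiment cannot be told apart there. The last count was 895 and 850 without PPARG WT replicates 1 and 2, 990 and 982 without EPAS1 WT replicates 1 and 3, and 4108 in a fit of these groups alone.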

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

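All values in this part come from the test of whether EPAS1 REV and WT responded differently to oxygen, planned before the results were seen; the groups of 3 libraries are too small to test single libraries for standing apart. GPRC5A, the retinoic acid-induced receptor gene, differed between the responses by -1.30 (adjusted p = 0.0025). It rose with 3% oxygen in WT, from 15.1 to 50.3 CPM, while in REV it was already at 41.4 CPM at 20% oxygen. In the fit of all 27 primitive syncytium libraries GPRC5A was not called (-1.29), while it was called under every other alternative run. The glycolysis list had a larger response in REV by a median log2 of 0.22, in addition to the 0.81 seen in WT. The mesenchyme and matrix list had a smaller response in REV by a median of -0.17. Neither list held a called member. Of 100 splits of the 12 libraries, 3 gave at least 1 interaction gene with the real one included, and the highest other split gave 6540. Most of these splits mix oxygen levels within a group, so the spread within groups holds the oxygen difference, and the share does not test chance for 1 gene. A split that calls so many genes points to a structure of the samples; which one was not tested. Of the same 100 splits, 66 gave at least 2 lists, and the highest other gave 8, so chance is not excluded for the lists.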

How the results depend on the processing

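The alternatives without line B01 and without line A05 were chosen after the data were seen; all other tests were planned. The 2 oxygen comparisons, PPARG REV against WT and the 2 contrasts with GCM1/GRHL1 WT stayed within 1.5 times under every alternative run. With each library of the compared groups left out in turn they gave 9197 to 9407 (oxygen, WT), 8590 to 10344 (oxygen, EPAS1 REV), 5076 to 5974 (PPARG), 9096 to 10295 (EPAS1 WT) and 8383 to 9372 (PPARG WT). The PAX6 counts kept within 1.5 times under every other setting run except where given below. With a library of the compared groups left out they ranged from 1995 to 3868 for KO against WT, 2475 to 4527 for KO against REV and 158 to 364 for REV against WT. Ranges of this kind were 41 to 507 for EPAS1 REV at 20% oxygen, 9 to 879 at 3% oxygen, 1 to 24 for the interaction, 1 to 3304 for GCM1 REV, 1 to 1 for GRHL1 REV (3132 without line B01 of GCM1 REV, a library of the same fit) and 850 to 1469 for PPARG WT against EPAS1 WT.

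Without a filter on low counts the counts were 731 (PAX6 REV, 403 with it), 906 (EPAS1 at 20% oxygen, 247), 1914 (3% oxygen, 81), 96 (interaction, 1), 1388 (GCM1, 546) and 91 (GRHL1, 1). DESeq2 gave 506 and 1138 for EPAS1 at 20% and 3% oxygen, 15 for the interaction, 2292 for GCM1 and 216 for GRHL1. Fits of the compared groups alone gave 759 for PAX6 REV, 493 and 4 for EPAS1 at 20% and 3% oxygen, 1 for GCM1, 2897 for GRHL1 and 4108 for PPARG WT against EPAS1 WT. All 27 primitive syncytium libraries in one fit gave 1390 (EPAS1, 3% oxygen), 5 (interaction, without GPRC5A), 3371 (GCM1) and 117 (GRHL1). RLE factors gave 140 at 3% oxygen. The estimated counts gave 31 for GCM1 and 2 for GRHL1, and GCM1 gave 1107 without robust estimation. Without line A05, EPAS1 gave 637 and 152 and the interaction 31; without line B01, GCM1 gave 1873. The cause of these shifts was not tested.

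With the line as a block the interaction gave 9 genes, and the cell cycle list in the REV oxygen response was no longer called. The block changed no other list call. It gave 10364 genes and 7 lists for oxygen in WT, where 9966 of 10102 calls kept their direction and side of the threshold, 9957 genes and 8 lists in REV (9535 of 9691) and 2 lists for the interaction. Parental libraries of different experiments share only a number, with correlations of -0.04 to 0.06, and a block for it gave 10867, 10907 and 4135 genes for EPAS1 WT and PPARG WT against GCM1/GRHL1 WT and PPARG WT against EPAS1 WT.

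With an estimated correlation, camera called 0 lists in each of the 11 comparisons with list tests. With fry, which compares no list with other genes, counts went from 3 to 6 (PAX6 KO against WT), 3 to 8 (KO against REV), 7 to 14 and 9 to 14 (oxygen in WT and REV), 8 to 0 and 4 to 1 (EPAS1 at 20% and 3% oxygen), 2 to 0 (interaction), 8 to 1 (GCM1) and 7 to 0 (GRHL1). It called 5 for PAX6 REV and 10 for PPARG, as many as camera. Shared PAX6 calls were 561 at an absolute log2 fold change of at least 1, and shared REV calls 30, or 164 with the estimated counts.

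For 378 named gene results, 5066 values were computed under alternatives. Of these, 4672 kept direction and side of the threshold, 385 kept direction but lost the call (285 of them with 1 library left out), 6 gained one and 3 turned. EPAS1 at 3% oxygen was 0.03 without the filter, EPAS1 in the REV oxygen response -0.09 to 0.12 with a library left out (lowest without REV replicate 3 at 20% oxygen), and PPARG in PPARG REV -0.08 to 0.00 (highest without REV replicate 3). None of the turned values was called. At the depth here, simulated changes of 0.5 were found in 49.3% to 83.6% of genes, so small changes are missed most often in the GCM1/GRHL1 experiment.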

Other observations

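The gene families, the interval on chromosome 20, the NLRP pair and the tests on reads of NLRP7 and NLRP2 and on the parental level of these genes were chosen after the results were seen; the other tests were planned. Replication-dependent histone genes, which are transcribed in S phase and read here in total RNA, were higher at 3% oxygen: 53 of 63 were called higher and 3 lower in WT (median log2 0.90; adjusted p = 0.48 with an estimated correlation), and 58 and 3 in EPAS1 REV (1.11; adjusted p = 0.40 with an estimated correlation). In organoids 40 of 67 were higher and 0 lower in PAX6 KO than in WT (0.26; adjusted p = 0.54 with an estimated correlation), and 55 and 1 against REV (0.48; adjusted p = 0.31 with an estimated correlation). Collagen genes were higher at 3% oxygen in 28 and lower in 2 of 36 in WT (0.93; adjusted p = 0.24 with an estimated correlation). Proteasome subunit genes were lower in 28 of 36 and higher in 0 (-0.50; adjusted p = 0.31 with an estimated correlation). Nuclear genes of the respiratory chain were lower in 47 and higher in 4 of 77 (-0.27; adjusted p = 0.48 with an estimated correlation), beside the fall of all 13 mitochondrial ones.

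Contractile and YAP-linked genes, to which ANKRD1 belongs, went opposite ways in reverted lines of different genes. They were higher in 11 and lower in 0 of 20 in EPAS1 REV at 20% oxygen (median 1.22; adjusted p = 0.14 with an estimated correlation), and higher in 3 and lower in 17 of 20 in PPARG REV (-1.02; adjusted p = 0.48 with an estimated correlation). ANKRD1 also differed between parental cultures. Cytosolic ribosomal protein genes were higher in 77 and lower in 3 of 82 in PPARG REV (0.40; adjusted p = 0.48 with an estimated correlation). Medians kept their sign with RLE factors.

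The raised run of genes on chromosome 20 in PPARG REV had a median of 0.48 over 15 genes, higher than 99.6% of runs of 15 neighbouring genes, where the highest other run reached 0.85. It was 0.48, 0.41 and 0.51 in lines A07, A08 and A09 and -0.20 to 0.17 in the other comparisons made. After regression on 3 of these comparisons the residual median was 0.63. The interval was chosen for its high values in PPARG REV, so this residual cannot decide on a cell state, shared or particular to these lines. Read assignment is argued against by a median of 0.48 with the estimated counts. A gained copy, for which the expected value is 0.58, may account for it, but the 21 genes of the interval under 1 CPM summed to 0.96, 0.12 and 0.55 over WT in the 3 lines, and with 114, 58 and 78 reads they leave it open.

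NLRP7 and NLRP2 were near absent in EPAS1 REV as in PPARG REV. NLRP7 was lower by -4.53 at 20% oxygen (adjusted p = 0.13) and -3.93 at 3% (adjusted p = 0.11), with line A05 at 4.42 CPM of the library total at 20% oxygen and A03 and A06 at 0, and differed by -0.21 and -0.13 in GCM1 and GRHL1 REV, where GCM1 lines B01, B06 and C04 held 24.3, 15.7 and 9.48 CPM against 20.5 in WT. Read assignment is argued against, since the estimated counts gave 5.03% and 2.25% of the parental level in EPAS1 and PPARG REV, and so is a difference between experiments, since the lowest parental library there held 46.9 CPM of the 2 genes and the highest reverted one 8.93. Loss of both copies in every cell is excluded for A05, whose libraries held 220 and 255 reads, and stays possible for A03 and A06, with at most 3 reads, and for A08 of PPARG REV, with 1 read of NLRP7, while A07 and A09 held 17 and 24. Silencing, and whether editing or cloning was involved, were not tested; of the neighbouring genes, GP6 fell in both (-2.31 in PPARG REV), while RDH13 (-0.85 and -1.72 at 20% and 3% oxygen) and EPS8L1 (-0.64 and -1.51) fell in EPAS1 REV and were at 0.13 and 0.23 in PPARG REV.

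Parental libraries of the GCM1/GRHL1 experiment differed from the other parental ones more than those did from each other. Long noncoding RNA genes lay further toward them than coding genes by a median log2 of -0.98 against EPAS1 WT and -0.85 against PPARG WT (3681 and 14549 genes), where random gene sets gave -0.04 to 0.04. PPARG WT and EPAS1 WT differed by 0.10. A larger share of nuclear or unspliced RNA may account for part of this, and reads in no annotated feature were 23.3% to 30.0% of uniquely mapped reads there against 10.1% to 17.7% in the other experiments. Depth is argued against, since in a fit of the 9 parental libraries alone the count of genes called between EPAS1 WT and GCM1/GRHL1 WT was 95.5% of its value with libraries thinned to 21.5 M reads (11395 to 10883), while culture differences between experiments were not tested.

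Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, so only values are given. For genes, the real split gave the highest count in all 13 comparisons of this kind: 1 of 10 splits gave as many. The highest other split gave 1 gene for PAX6 KO against REV, EPAS1 REV at 20% and at 3% oxygen and oxygen in EPAS1 REV, and 0 elsewhere. Where line or number pairs the oxygen libraries, the real split parts all 3 pairs, and the other splits that part 3 pairs gave 0 genes with edgeR, as did those that part 1 pair, but for the split with 1 gene in REV. For lists, the real value, the highest other and the splits with as many of 10 were 3, 3 and 2 for PAX6 KO against WT, 3, 4 and 2 for KO against REV, and 5, 5 and 2 for PAX6 REV. They were 8, 9 and 3 for EPAS1 REV at 20% oxygen, 4, 5 and 3 at 3% oxygen, 7, 7 and 4 for oxygen in WT and 9, 8 and 1 in REV. They were 8, 9 and 4 for GCM1, 7, 6 and 1 for GRHL1 and 10, 9 and 1 for PPARG. For shared calls, of 100 splits, 1 gave as many as the 2356 of PAX6 (highest other 1843), and 1 as many as the 439 of the reverted lines (highest other 221). Splits that call few genes can share few, so this does not test whether sharing exceeds that of independent lists.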
